A study of Homo sapiens with 7 samples.

How the data were processed

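The samples were 7 subcutaneous tumours grown in athymic nude mice from Panc-1, a human pancreatic carcinoma cell line. Of these, 4 came from cells with a control shRNA and 3 from cells with an shRNA against GSK3B, glycogen synthase kinase 3 beta. Per the labels, cells were implanted under the skin on both flanks of each mouse, tumours were grown to at least 250 mm3 and microdissected, and total RNA was labelled with biotin. Each tumour has its own Affymetrix HG-U133 Plus 2 array with 54675 probe sets. The labels name the group and replicate number of each array, and the array columns of the deposited tables were matched to samples by those labels.

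Per the file headers, the authors summarised each probe set as a trimmed mean of perfect-match minus mismatch intensities. They scaled it and matched its quantiles to those of control replicate 1. They then added an offset, floored the result and took log2. The deposited values are therefore log2 expression values with a lowest possible value of 5.64, and a probe set with no signal over mismatch sits at 6.64. Because of that offset, fold changes of dim genes are understated. Between 384 and 405 probe sets per array lay at the floor. The authors also deposited their own table with a fold (ratio) per probe set and an unadjusted p-value of a two-sample test with equal variances. Those p-values and folds were recomputed from the array columns to within 3.5e-09 and 3.6e-15. A second deposited table held the same log2 values to within 5.0e-09. The authors' quality sheet gave the background, a brightness slope, the number of probe sets detected and the 3' to 5' ratio of actin for each array. Versions of the authors' software are not given in the sources used here.

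Gene symbols came from the Affymetrix annotation columns of the deposited table and were updated through gene identifiers of the RefSeq table of assembly GRCh38.p14, which served only for names and for the order of neighbouring genes. Of the 54613 probe sets left after removing 62 Affymetrix control probe sets, 40841 had one symbol, 938 had several and 12834 had none. Of those with one symbol, 39780 matched the RefSeq table, 5953 of them under a newer symbol, and 1061 kept the symbol of the file. A gene was represented by its probe set with the highest mean over the 7 arrays, which gave 19989 genes. Probe sets with several symbols were tested but not named.

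Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on the deposited log2 values of all 7 arrays, with the group as the only term. The p-values are two-sided and adjusted by the Benjamini-Hochberg method over 54613 probe sets, with a threshold of 0.05. A called probe set, gene or list is one below that threshold. The model had 5 residual degrees of freedom and gained 4.01 from the shared variance. For GSK3B and GSK3A, an exact two-sided permutation test over the 35 splits of the arrays was added; the smallest p it can give is 0.0571.

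Of 34 gene lists fixed before the data were examined, 33 had at least 5 members and were tested with limma's camera at its preset correlation of 0.01, beside camera with an estimated correlation and limma's fry. Of 854 listed genes, 842 were on the array. The lists covered GSK3-related pathways, tumour programs, and host cells that a flank tumour could hold.

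Genes named in the text followed a rule fixed before the data were examined. It took all probe sets of GSK3B and GSK3A. It took the 12 called genes that rose and the 12 that fell most, if the brighter group lay above the median of all probe sets and the groups did not overlap. From each list it took up to 4 called members by smallest p, or the 2 largest changes as values where fewer than 2 were called. Some list members that the rule takes are not reported here. The pool for the largest changes held 100 rising and 57 falling genes.

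The fit was tested on simulated data for GSK3B shRNA versus control shRNA, with 54613 probe sets and 200 of them changed in each of 20 simulations. It recovered 89.57% of 2-fold and 99.79% of 4-fold changes, with 5.025% false calls. For lists, 60 of 60 simulated shifts of 0.3 log2 over 19989 genes were recovered, with 6 false calls. The simulated noise was normal and independent between probe sets, with variances taken from the fit itself. Only probe sets above the median mean were changed, and only lists of at least 20 members were shifted. In the data, genes of a list vary together (estimated correlation up to 0.49), so the rates for lists do not carry over to them.

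Alternatives covered the normalization, the second table, a filter on dim probe sets, the variance model, array weights, the replicate number as a block, the summary of probe sets per gene, the threshold, the test without shared variance, the list test, and each array left out in turn. The deposited values were already matched in quantiles and the second table repeats them, so the normalization and that table could change little. Removal of the authors' offset and the array brightness as a covariate were added after seeing the data. With the offset removed, values that fell below 5.64 on the log2 scale were set to 5.64. The number of arrays limits the precision. The labels do not say which tumours shared a mouse, so p-values measure the spread between these samples. Tables, checks of the files and figures used Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 beside R.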

Results

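Transcript levels were measured in 7 Panc-1 xenografts, 4 carrying a control shRNA and 3 carrying an shRNA against GSK3B, a serine/threonine kinase that acts in Wnt, insulin and stress signalling. Values are the authors' log2 expression values, given as mean ± SD over 4 control and 3 GSK3B shRNA tumours unless stated. Per array, between 30456 and 32299 probe sets were detected, and the mean number did not separate the groups (31335.5 in control and 31674.7 in GSK3B shRNA tumours, exact permutation p = 0.571). Arrays of the control group correlated at r = 0.979 to 0.984 across probe sets, those of the GSK3B group at 0.979 to 0.980, and arrays of different groups at 0.971 to 0.979. Probe sets are not independent replicates. The authors' brightness slope was 0.272 ± 0.0233 in the control and 0.222 ± 0.0039 in the GSK3B shRNA arrays, which did not overlap (exact permutation p = 0.0571, two-sided by doubling, the smallest that this test can give here). A range after a gene that did not pass is over fits with single arrays left out, and is given where the value moved by more than 1.5 times.

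The first question was whether the targeted transcript was reduced. GSK3B was lower in all 3 GSK3B shRNA tumours than in all 4 control tumours. Its representative probe set, 226191_at, fell from 11.36 ± 0.08 (SD, n = 4) to 9.63 ± 0.19 (SD, n = 3), a log2 fold change of -1.73 (SE 0.12, 3.32-fold; limma adjusted p = 0.00352; exact permutation p = 0.0571, the smallest this test can give). About 30.12% of the control signal was left on the authors' scale. With the replicate block, without shared variance and with brightness as a covariate the change was -1.76, -1.73 and -1.60. In these fits GSK3B did not pass (adjusted p = 0.0751, 0.0654 and 0.538). Of the other probe sets of GSK3B, 209945_s_at fell by 1.37 (adjusted p = 0.00595) and 226183_at fell by 1.95 (adjusted p = 0.00595). Probe set 242336_at had a log2 fold change of -0.62 (adjusted p = 0.157), and 240562_at, near the level of no signal, one of 0.29 (adjusted p = 0.462). GSK3A, the paralogous kinase, did not pass, with log2 fold changes of -0.23 for 632_at (95% interval -0.54 to 0.07, adjusted p = 0.437) and -0.18 for 202210_x_at (95% interval -0.53 to 0.16, adjusted p = 0.607).

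**Figure D1:**
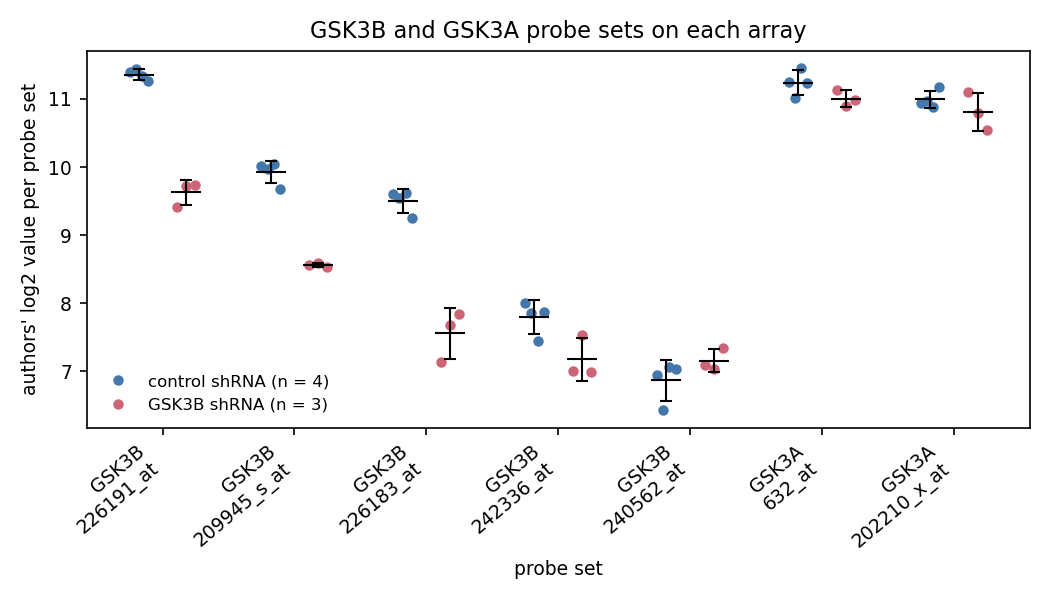
Authors' log2 values of each GSK3B and GSK3A probe set on each array (points; bars are mean ± SD, n = 4 control and n = 3 GSK3B shRNA). At 226191_at the GSK3B shRNA arrays lie between 9.41 and 9.74, below the control arrays at 11.27 to 11.44.

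The second question was which other transcripts differed. HGF, the ligand of the MET receptor, rose from 7.05 ± 0.29 to 10.89 ± 0.88 (log2 fold change 3.84, SE 0.35, 14.36-fold; adjusted p = 0.00595). All 5 of its probe sets rose, by 3.39-fold to 14.36-fold, with the largest rise on the representative. Its control values, 6.71 to 7.36, lie near the level of no signal, 6.64, so the fold depends on the authors' offset, as it does for TMEM255A and TTC9B below, with control means of 7.01 and 7.34. TNFRSF11B, which encodes the decoy receptor osteoprotegerin, rose by 3.22 on the log2 scale (9.31-fold, adjusted p = 0.00675). Other genes that rose were the regulators of G-protein signalling RGS4 (log2 fold change 2.92, adjusted p = 0.0483) and RGS2 (2.59, adjusted p = 0.00993), the protease inhibitor TFPI2 (2.66), the neuroendocrine secretory protein SCG2 (2.55), the fibrillar collagen COL5A2 (2.54, adjusted p = 0.00636) and the G-protein subunit GNG4 (2.25). RGS4, TFPI2 and GNG4 each passed in 1 of 7 fits with an array left out. HMOX1, the haem-degrading enzyme, rose by 2.13 (4.37-fold, adjusted p = 0.00387) and TMEM255A by 2.08. TTC9B rose by 2.23 and the matrix protein TNC by 2.12 (adjusted p = 0.00547), but the second probe set of each showed little difference (0.09 and 0.13). Group means of these second probe sets, 6.91 to 7.09, lie near the level of no signal, so they say little about the rises.

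In the other direction, the complement component C3 fell from 10.09 ± 0.35 to 7.99 ± 0.12 (log2 fold change -2.09, SE 0.19, 4.26-fold; adjusted p = 0.00595). GLUL, glutamine synthetase, fell by 2.04 (adjusted p = 0.0021), the raft protein RFTN1 fell by 1.85, although its other probe set stood at -0.11, and the guanine nucleotide exchange factor ARHGEF6 fell by 1.85 (adjusted p = 0.00387). MATN2 fell by 1.59, GSAP fell by 1.45 (adjusted p = 0.0489) and THY1, a surface glycoprotein of fibroblasts among other cells, fell by 1.43, as did both of its other probe sets. NBL1 fell by 1.25, C1orf226 fell by 1.18, ST6GALNAC2 fell by 1.17 and VSTM2L fell by 1.15.

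**Figure D2:**
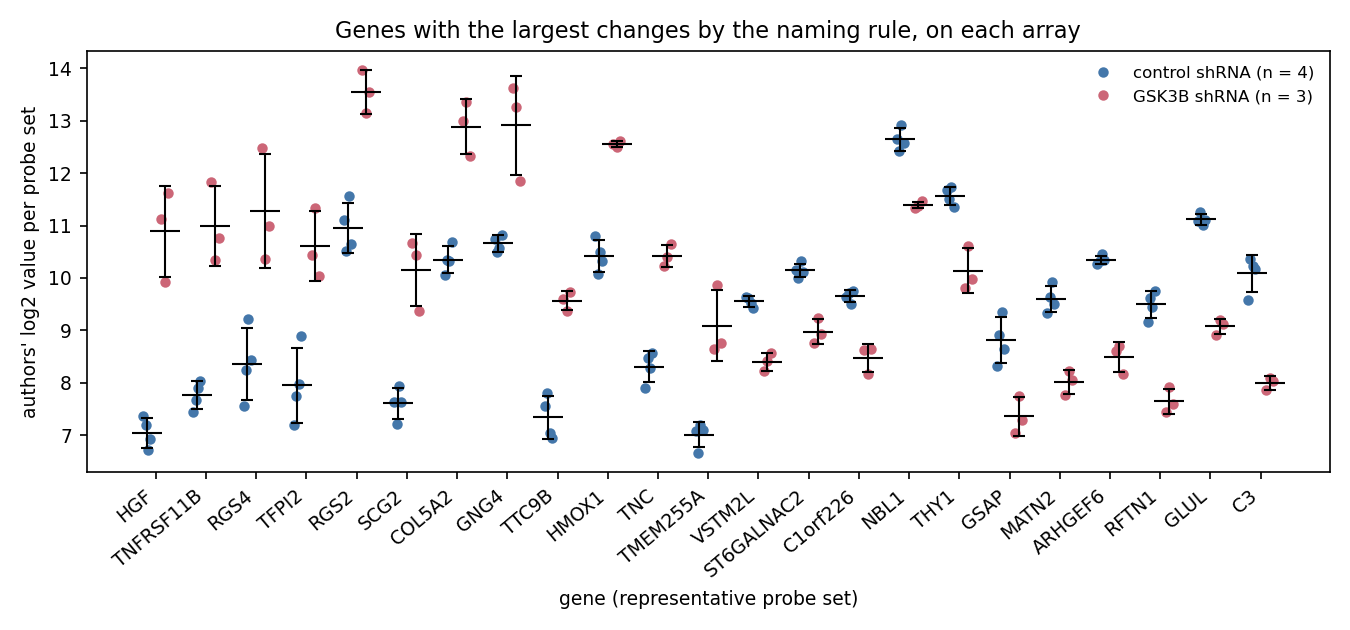
Authors' log2 values on each array for the genes with the greatest changes by the naming rule, apart from GSK3B (points; bars are mean ± SD, n = 4 control and n = 3 GSK3B shRNA). HGF means rise from 7.05 to 10.89 and C3 means fall from 10.09 to 7.99, with no overlap between groups for any gene shown, which the rule requires.

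Across the array, 346 of 54613 probe sets passed an adjusted p of 0.05 in limma, 242 higher and 104 lower in GSK3B shRNA tumours. By representative probe set these were 162 of 19989 genes, 104 higher and 58 lower. The median fold of the called probe sets was 2.24 among those higher and 1.86 among those lower. In all 346 called probe sets the groups did not overlap, against 15.95% of all probe sets and 5.714% by chance. The threshold favours probe sets whose groups lie apart, so the share among called ones adds no support to the calls. Of the 203 probe sets in the strictest-p selection at over 1.5-fold in the authors' deposited table, 170 were also called here. The count fell to 56 without control replicate 1, 66 without control replicate 2, 72 without control replicate 3, 80 without control replicate 4, 64 without GSK3B replicate 1 and 127 without GSK3B replicate 3. Of the called genes named here, 17 of 34 passed in each of these fits and in that without GSK3B replicate 2: GSK3B, HGF, TNFRSF11B, RGS2, COL5A2, TTC9B, HMOX1, TNC, C3, GLUL, RFTN1, ARHGEF6, MATN2, VSTM2L, SLC2A1, HK2 and FAS. Those that passed in 1 of the 7 were RGS4, TFPI2, GNG4, GSAP, THY1, ERO1A, SMAD6, HEY1 and COL1A1, and BTRC and NEU1 passed in 0. NBL1 passed in 6, SCG2 in 4, TMEM255A and C1orf226 in 3, and ST6GALNAC2 and EPHA4 in 2. With the array brightness as a covariate no probe set passed in limma (4387 had an unadjusted p under 0.05), and without shared variance 5 passed.

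**Figure D3:**
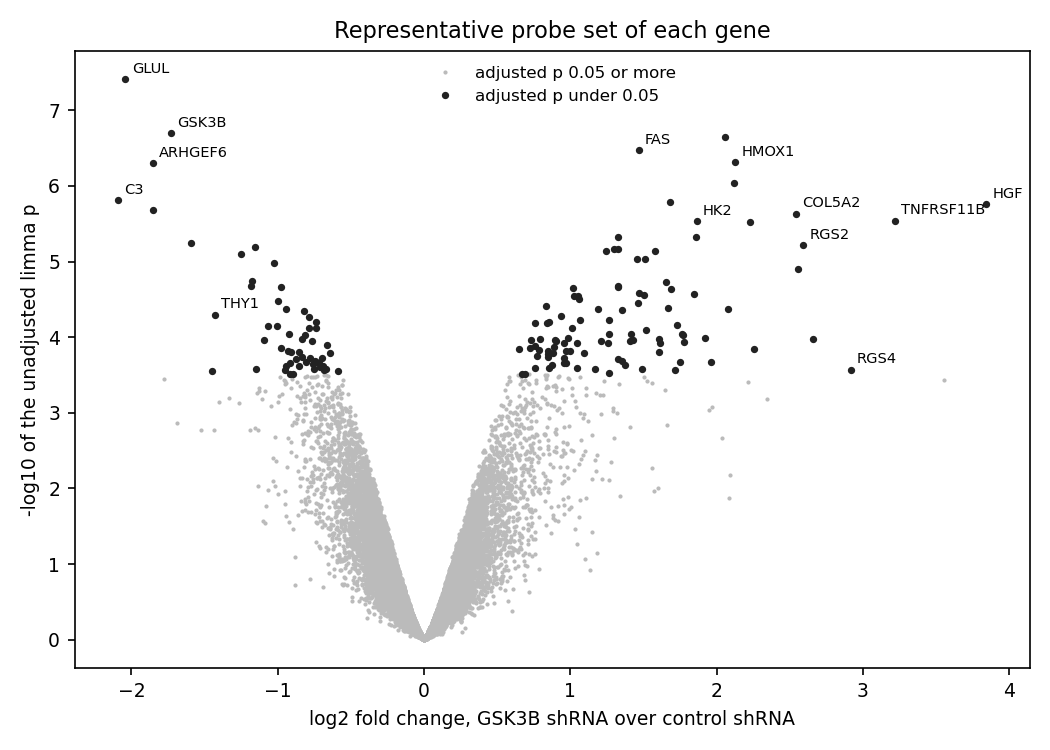
Log2 fold change of each gene's representative probe set (x) against the -log10 of its unadjusted limma p (y), with called genes in black. Of 162 called genes, 104 lie to the right and 58 to the left.

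The third question was whether gene lists fixed before the data were examined shifted as a set. Of 33 lists, 11 passed camera at its preset correlation, and none of them passed with an estimated correlation. Genes induced by hypoxia rose as a list (24 of 27 higher, median log2 fold change 0.30; adjusted p = 4.39e-08; adjusted p = 0.539 with an estimated correlation). SLC2A1, a glucose transporter, rose by 1.33 and ERO1A, an oxidase of the endoplasmic reticulum, by 1.09, and 10 members passed when adjusted over the list alone. Among genes of glycolysis and glycogen, 19 of 29 were higher (adjusted p = 0.0216; adjusted p = 0.539 with an estimated correlation). HK2, a hexokinase, rose by 1.86 and was its single called member, with 3 passing adjusted over the list alone. The list did not pass with the replicate block (adjusted p = 0.0621) or without GSK3B replicate 1 or 3. PPP1R3B stood at 0.65 (adjusted p = 0.0845).

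Genes of mitosis and proliferation were higher in 29 of 30 cases (median 0.22; adjusted p = 1.93e-07; adjusted p = 0.244 with an estimated correlation), with 0 members called and 7 adjusted over the list alone. MKI67 stood at 0.66 (adjusted p = 0.0904), with its other 3 probe sets at -0.12 to 0.09, and CCNE2 at 0.52 (adjusted p = 0.067). DNA replication genes were higher in 26 of 30 cases (adjusted p = 5.22e-05; adjusted p = 0.544 with an estimated correlation), with 0 called and 0 adjusted over the list alone. GINS4 stood at 0.59 (range 0.30 to 0.88) and ORC1 at 0.46. With brightness as a covariate the list mean turned from 0.19 to -0.034 (adjusted p = 0.84), GINS4 to -0.21 and ORC1 to -0.040. In the unfolded protein response list 20 of 24 were higher (adjusted p = 5.22e-05; adjusted p = 0.42 with an estimated correlation), with 0 called and 7 adjusted over the list alone. TRIB3 stood at 0.92 (adjusted p = 0.0505) and DDIT3 at 0.96 (adjusted p = 0.0846).

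Wnt/beta-catenin targets, of interest because GSK3 marks beta-catenin for degradation, were higher in 22 of 34 cases (median 0.10; adjusted p = 0.0233; adjusted p = 0.539 with an estimated correlation). With brightness as a covariate the list mean turned from 0.18 to -0.011 (adjusted p = 0.62). The list did not pass with the mean of all probe sets of a gene (0.0536), with representatives by interquartile range (0.0688), or without control replicate 2 or GSK3B replicate 1. None of its members was called by its representative probe set. Adjusted over the list alone, 8 passed as higher and 3 as lower. TNFRSF19 stood at 1.97 (adjusted p = 0.0683) and JAG1 at 0.84 (adjusted p = 0.0542), while another probe set of JAG1 rose by 0.99 (adjusted p = 0.0388). Wnt pathway components did not shift (adjusted p = 0.867; mean 0.02 and median -0.04, with the test pointing down), although BTRC, which encodes the ubiquitin ligase subunit that binds phosphorylated beta-catenin, fell by 0.67 on 1 of its 5 probe sets (adjusted p = 0.0366). Its other 4 stood at -0.34 to -0.03, none called, and it did not pass in any fit with an array left out. Adjusted over the list alone, 2 passed, both lower, and WNT11 stood at 1.15 (adjusted p = 0.152).

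The mesenchymal list was higher (18 of 27; adjusted p = 0.00203; adjusted p = 0.372 with an estimated correlation). TNC was called, FN1 stood at 1.30 (range 0.85 to 1.62, adjusted p = 0.0958), and 9 were higher and 1 lower adjusted over the list alone. TGF-beta targets were higher in 16 of 24 cases (adjusted p = 0.0233; adjusted p = 0.372 with an estimated correlation). Its single called member, the inhibitory SMAD6, fell by 1.15 (adjusted p = 0.0479). It passed in 1 of 7 fits with an array left out, and its other 3 probe sets stood at -0.69 to 0.02, none called. ID3 stood at 0.96 (range 0.57 to 1.16, adjusted p = 0.227), and 4 were higher and 1 lower adjusted over the list alone. ERK pathway targets were higher in 17 of 26 cases (adjusted p = 0.0213; adjusted p = 0.539 with an estimated correlation). Its single called member, the ephrin receptor EPHA4, fell by 0.98. EPHA4 passed in 2 of 7 fits with an array left out, and its other 4 probe sets stood at -0.75 to -0.31, none called. EREG stood at 2.34 (adjusted p = 0.0633), and 6 were higher and 1 lower adjusted over the list alone. NRF2 targets were higher in 19 of 28 cases (adjusted p = 0.0233; adjusted p = 0.553 with an estimated correlation). With brightness as a covariate their mean turned from 0.17 to -0.021 (adjusted p = 0.923), and the list passed in 3 of 7 fits with an array left out. HMOX1 was called, SLC7A11 stood at 1.11 (adjusted p = 0.0611), and 3 were higher and 1 lower adjusted over the list alone. Fatty acid synthesis genes were lower in 11 of 14 cases (median -0.30; adjusted p = 0.0233; adjusted p = 0.372 with an estimated correlation), with 0 called and 1 lower adjusted over the list alone. ELOVL6 stood at -1.40 (adjusted p = 0.0657) and SREBF1 at -0.45 (adjusted p = 0.197). FN1, SLC7A11 and ELOVL6 each had another probe set that passed in the same direction. With brightness as a covariate the means of the mesenchymal (from 0.32 to 0.13, adjusted p = 0.271), ERK (0.27 to 0.077, 0.271) and TGF-beta (0.13 to 0.043, 0.351) lists shrank, and these lists did not pass. The fatty acid mean was -0.27 before and -0.28 after, and its call ended as well (0.247). With the mean of all probe sets of a gene the ERK (0.0593), NRF2 (0.0593), TGF-beta (0.0568) and fatty acid (0.0979) lists did not, nor did TGF-beta (0.188) and NRF2 (0.138) targets with representatives by interquartile range. By fry, 3 of the 11 lists passed, mitosis (adjusted p = 0.00939), mesenchymal genes (0.048) and fatty acid synthesis (0.0422).

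The host lists did not pass with the settings used throughout. The fibroblast and matrix list had an adjusted p of 0.0715 (14 of 26 higher, median 0.07; 0.0203 among brighter probe sets and 0.0308 with a variance trend), with COL5A2 and COL1A1 (1.33, adjusted p = 0.0417) called higher and THY1 called lower. Adjusted over the list alone, 9 were higher and 3 lower. Endothelium and pericytes had an adjusted p of 0.358 (ENG at 0.62 and TIE1 at 0.41). Macrophages and leukocytes had one of 0.358 (16 of 23 lower, median -0.23; 0.0215, the list lower, with brightness as a covariate; among the members with the greatest changes, CD68 at 0.64, range 0.46 to 0.96, and S100A9 at 0.73, range 0.27 to 0.99), erythroid cells one of 0.358 (EPB42 at 0.31, range 0.16 to 0.43, and HBB at 0.26, range 0.039 to 0.37). Adipocytes had one of 0.375 (CFD at -0.39, range -0.53 to -0.23, and LPL at -0.38), skeletal muscle one of 0.56 (MB at -1.13 and TNNI2 at -0.49, range -0.79 to -0.18). Skin keratinocytes had one of 0.689 (KRT14 at -0.88, range -1.14 to -0.21, the latter without control replicate 4, and DSC1 at 0.55, range 0.021 to 0.96; median -0.07, mean -0.03, test pointing up). Adjusted over the list alone, 1 muscle gene passed, lower, and 0 passed in the other 5 of these lists.

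The remaining lists did not pass either with those settings. MYC targets and ribosome biogenesis had an adjusted p of 0.117 (PA2G4 at 0.31, GNL3 at 0.28), epithelial genes one of 0.194 (DSP at 1.60, range 0.93 to 2.23). Apoptosis regulators had one of 0.223 (BCL2A1 at 0.66, BIRC5 at 0.52), cytosolic ribosomal proteins one of 0.246 (0.0238 with the offset removed; RPL4 and RPL14 at 0.14 and 0.13). Interferon-stimulated genes had one of 0.295 (MX1 at -0.61, range -1.09 to -0.078, IFI27 at 0.61, range -0.037 to 1.17) and DNA repair one of 0.312 (RAD51AP1 at 0.66, FANCD2 at 0.46). Autophagy and lysosome had an adjusted p of 0.358 (NEU1, a sialidase, rose by 0.97 with an adjusted p of 0.0388 and passed in 0 of 7 fits with an array left out, and GLA stood at -0.38). Cholesterol biosynthesis and uptake had one of 0.358 (STARD4 at 0.77, INSIG1 at 0.70), NF-kB targets one of 0.375 (0.000526, the list lower, with brightness as a covariate; CCL2 at -1.69, LTB at -0.999). Hedgehog targets had one of 0.625 (FOXL1 at 0.60) and pancreatic acinar and endocrine genes one of 0.625 (PRSS2 at 0.79, range 0.19 to 1.39, CEL at -0.52). The Notch list had an adjusted p of 0.625 (median -0.02, mean 0.08, test pointing up), with HEY1, a Notch effector, higher by 1.41 (adjusted p = 0.035). The p53 list had an adjusted p of 0.796 (median -0.08, camera pointing down and fry up), with the death receptor FAS higher by 1.47 (2.76-fold, adjusted p = 0.00369) on all 4 probe sets and TP53I3 at -0.57. Oxidative phosphorylation had an adjusted p of 0.821 (0.0058, the list lower, with brightness as a covariate; mean and median below 0, camera pointing up and fry down; NDUFV2 at 0.26, SDHA at -0.23). Adjusted over the list alone, 3 NF-kB genes passed as lower, 3 p53 genes as higher and 4 as lower, 2 Notch and 2 cholesterol genes as higher, 1 gene each of DNA repair and of autophagy as higher, and 0 in the other 8 of these lists.

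**Figure D4:**
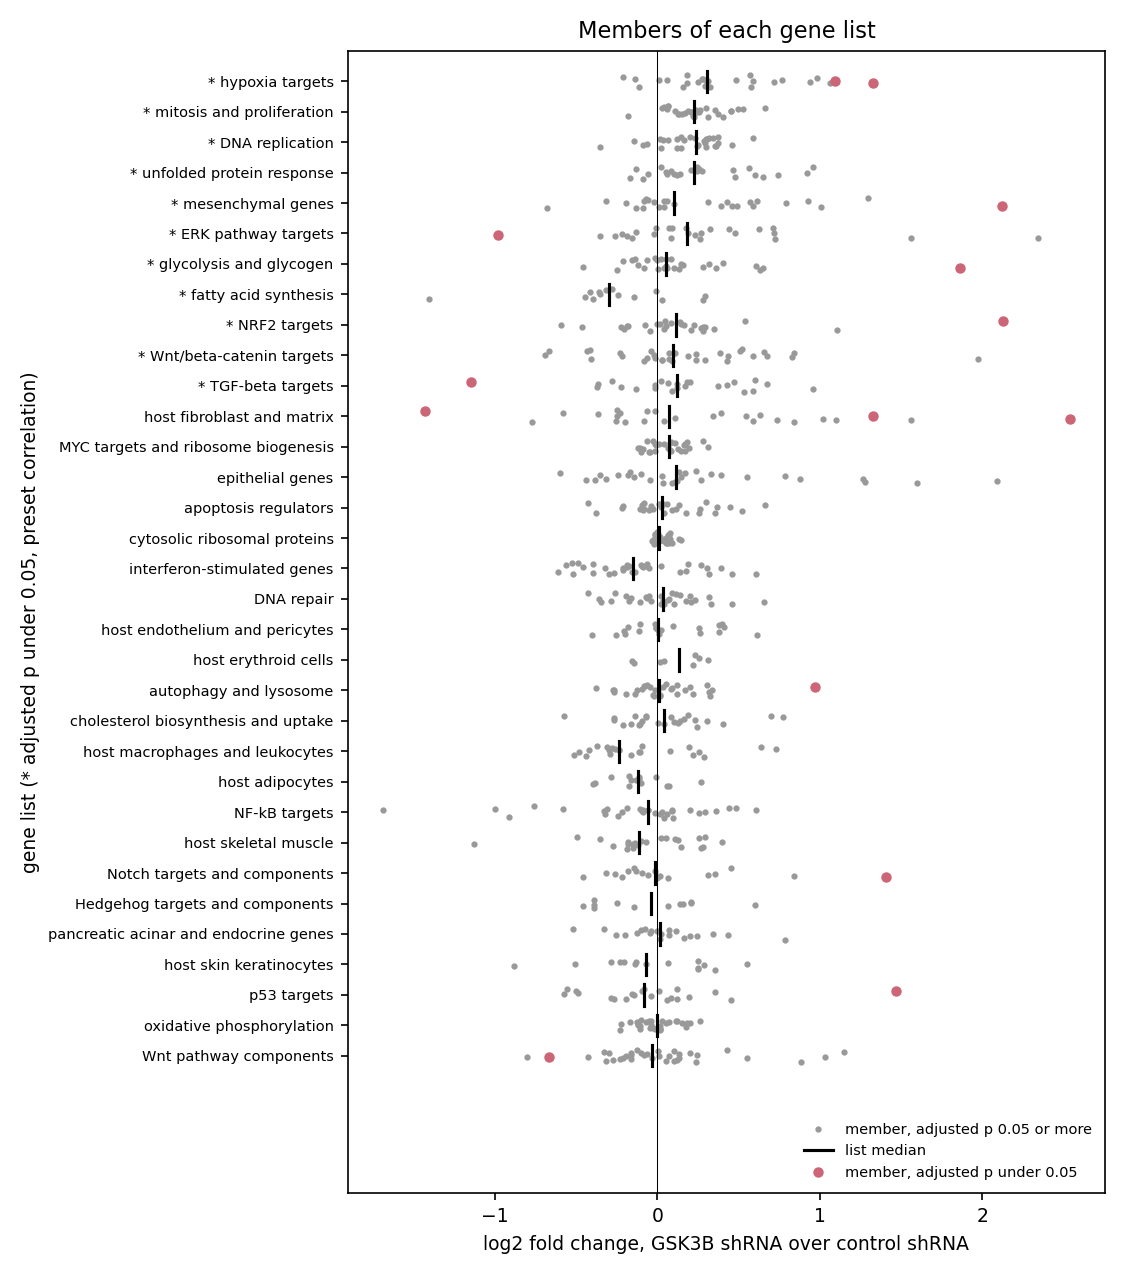
Log2 fold change of each member of 33 gene lists (points; red points are called members, black bars list medians, an asterisk marks a list with adjusted p under 0.05 at the preset correlation). Hypoxia targets have a median of 0.30 and fatty acid synthesis one of -0.30.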

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

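The tests of array brightness, inter-gene correlation, host tissue and fibroblasts were chosen only after the results were seen, and those over the splits of the arrays before.

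The pattern weighed first was the 346 probe sets that differed between the groups. Of the 35 splits of the 7 arrays into 3 and 4, 1 gave as many, the real one, and the highest of the others gave 0. Counted without direction, this excludes chance in the grouping at 0.05 only if the arrays could be swapped between groups. Tumours that shared a mouse could not, and the labels do not name them. Every other split mixes the groups, so a group difference widens the spread there and lowers the count. The GSK3B shRNA arrays had the lower brightness slopes, and with brightness as a covariate 0 probe sets passed. That correction left 0.947 of the median change of the 346 probe sets (1.03 before and 0.97 after on the log2 scale; 0.913 to 0.955 with an array left out), all 346 kept their sign, and the calls ended because the standard error of the group difference grew 1.90-fold. These probe sets were picked for a large difference beside a small spread within groups, from which the effect of brightness is estimated. Much of their change was thus bound to stay, and the correction cannot tell brightness from the group. Brightness, a difference between the stable cell lines unrelated to GSK3B and the knockdown itself, the biological difference in the design, stay open and were not told apart. The files used here name no hybridisation or scan batch, so none was tested, and the spiked-in probe sets differed by a median of 0.09 on the log2 scale.

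The second pattern was the 11 gene lists past the threshold. Of the 35 splits, 2 gave as many, with 11 lists in the real split and 11 in the highest other, so chance in the grouping cannot be excluded. Camera with an estimated correlation, in which 0 of the 11 passed, also cuts the degrees of freedom to 5, and at the preset correlation that cut alone left 2. With each list's estimated correlation put in and nothing else changed, 1 of the 11 passed, mitosis (adjusted p = 0.000458). For 10 of the 11 lists the estimate lay above the preset 0.01, which is consistent with genes of a list varying together between tumours more than the preset correlation assumes. This does not hold for TGF-beta targets (estimate -0.0017, adjusted p = 0.0522 as fewer other lists passed), the estimates rest on 5 degrees of freedom, and the knockdown stays open, not tested apart from the grouping.

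The third pattern was the higher collagen transcripts, COL5A2 and COL1A1, with a mean log2 fold change of 1.93. If the GSK3B shRNA tumours held more mouse tissue of every kind, genes of the other host lists should rise as well. Over 44 bright genes of those lists the median log2 fold change was -0.10 (95% bootstrap interval -0.17 to 0.06). The interval resampled genes and not tumours, so it leaves out the spread between tumours. It lay below the bound of 0.97, set from the 2 collagens called in the same data. The comparison shows only that these genes as a group did not rise as much as collagens picked for their rise. If they held more fibroblasts of the general kind, genes of that list should rise alike. Over its 20 bright genes, the collagens included, the median was 0.25 (-0.07 to 0.79, by the same resampling), also below the bound. Of these genes, 12 were higher and 8 lower, and THY1 fell by 1.43 on its representative probe set. By camera the list passed as higher among brighter probe sets (adjusted p = 0.0203) and with a variance trend (0.0308), but not with the settings used throughout (0.0715). How well the human probes read mouse transcripts is not known, so these medians cannot exclude more host tissue or more fibroblasts. A change in the kind of fibroblast or expression by the tumour cells may also account for the rise, and all of these stay open.

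Single values were also apart. In the control tumours, KRT14 stood at 9.56 in replicate 4 against 6.74 to 7.10 in the others (its change of -0.88 becomes -0.21 without that array), and BCL2A1 at 9.57 in replicate 1 against 10.13 to 10.24. These were 2 of 91 values tested for an array far from the rest of its group, fewer than the 5% that chance gives. Among control probe sets for spiked-in transcripts, which no comparison used, 7 of 18 were higher on every GSK3B shRNA array than on every control array. None of the 18, a count of 0, was lower on every GSK3B shRNA array. The median difference of the 7 was 0.14 and the highest 0.23 on the log2 scale (0.09 is the median over all 18). Most of the 7 read the same spiked-in transcript, bioB, so they are not separate observations.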

How the results depend on the processing

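Offset and brightness fits were added after seeing the data. Array weights (417 probe sets) changed no call of the 34 called genes or the lists. Quantile normalization (343), centring and the second table hardly could, and did not. The 346 calls became 1884 among brighter probe sets, not from fewer tests alone, and 1946 with a variance trend. There were 187 at 2-fold or more and 35 at an adjusted p of 0.01. Without shared variance 5 passed, 3 among the 346 (8260 at an unadjusted p under 0.05). With the offset removed there were 320, of which 123 were shared, and 20 of the 34 called genes kept their call while 14 lost it. The 3 shared replicate numbers did not pair the tumours (r of their deviations -0.0992, 0.0618 and 0.0768). With the replicate block 0 probe sets passed in limma. GSK3B stood at -1.76 with the replicate block (adjusted p = 0.0751), -1.73 without shared variance (0.0654) and -1.60 with brightness (0.538; range over its alternatives from 4.34e-06), where 0 probe sets passed because its precision fell. The causes of the other changes were not tested. The 11 lists became 10 with the replicate block (glycolysis lost) and 8 by interquartile range (Wnt, TGF-beta and NRF2 targets lost). They became 6 with the mean of all probe sets of a gene, 0 with an estimated correlation, 3 by fry and, with brightness, 7, of which 4 were among the 11. The other 3 were NF-kB targets (-0.47, adjusted p = 0.000526), macrophages (-0.35, 0.0215) and oxidative phosphorylation. Of the 7 that brightness ended, the means of DNA replication (-0.034), Wnt targets (-0.011) and NRF2 targets (-0.021) turned sign. Fibroblasts passed among brighter probe sets (0.43, adjusted p = 0.0203) and with a variance trend (0.0308), and ribosomal proteins with the offset removed (0.0238). Leaving out single arrays gave 56 to 276 probe sets, GSK3B at -1.79 to -1.62 (called in all 7 fits) and 8 to 11 lists, with fewer arrays in each fit. Hypoxia, mitosis, DNA replication, the unfolded protein response and mesenchymal genes passed in all 7. Wnt targets did not without control replicate 2 or GSK3B replicate 1 (highest adjusted p 0.0656), glycolysis without GSK3B replicate 1 or 3 (0.0787), TGF-beta targets without GSK3B replicate 2 (0.105). Fatty acid synthesis did not without GSK3B replicate 3 (0.0707), ERK targets without GSK3B replicate 1 (0.0893) and NRF2 targets without control replicate 1 or 2 or GSK3B replicate 1 or 3 (0.0893). Interferon-stimulated genes passed without GSK3B replicate 2, epithelial genes and skeletal muscle without GSK3B replicate 3, and fibroblasts without GSK3B replicate 1 or 3. Of the 34 called genes, 17 passed in all 7 fits, 15 in some, and BTRC and NEU1 in none. The direction of a list's test or of a gene's log2 fold change turned in 34 cases, 33 of them past the threshold in neither fit. For pancreatic genes, Wnt components, oxidative phosphorylation, keratinocytes, Notch, p53 targets by fry and autophagy by interquartile range, the test turned while the list mean kept its sign. Values are log2 fold changes, or means of them for lists. With brightness, oxidative phosphorylation stood at -0.21 (adjusted p = 0.0058), GINS4 at -0.21, ORC1 at -0.040, NDUFV2 at -0.13, cholesterol genes at -0.093, MYC targets at -0.053, apoptosis at -0.063, Hedgehog at 0.017, autophagy at -0.086 and keratinocytes at -0.34. Among brighter probe sets, p53 targets stood at 0.0074 and pancreatic genes at 0.035. With the replicate block, Wnt components stood at 0.043 and muscle at 0.0039. With all probe sets averaged, Wnt components stood at 0.049. By fry, p53 targets (-0.025) and oxidative phosphorylation (-0.0051) turned. By interquartile range, Wnt components stood at 0.087, p53 targets at 0.056, Hedgehog at 0.048 and autophagy at 0.018. Without the offset, EPB42 stood at 0 and oxidative phosphorylation at -0.0048. With single arrays left out, IFI27 ranged from -0.037 to 1.17, Notch from 0.0040 to 0.14, Wnt components from -0.011 to 0.043, muscle from -0.29 to 0.065, keratinocytes from -0.14 to 0.060, interferon-stimulated genes from -0.28 to 0.099 and oxidative phosphorylation from -0.056 to 0.029. Signal near background limits dim genes, whose folds the offset understates.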

Other observations

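The genes in this paragraph were chosen after their values were seen, and the test of chromosome segments was set before its result was seen. A probe set of GNAI1 other than its representative rose by 1.61 (adjusted p = 0.0236), while the representative, at 1.53, did not pass (adjusted p = 0.0522). RGS17 rose by 0.89 (adjusted p = 0.035). ANPEP, a cell surface enzyme, rose by 1.30 (adjusted p = 0.01) and NT5E, which makes adenosine outside the cell, by 1.25 (adjusted p = 0.01). F3, the tissue factor that starts coagulation, rose by 1.32 (adjusted p = 0.018). The secreted hormone STC1 rose by 1.67 (adjusted p = 0.0239). A probe set of ANGPTL4 other than its representative rose by 1.27 (adjusted p = 0.0439), while the representative, at 1.06, did not pass (adjusted p = 0.0505). The adhesion molecule L1CAM fell by 1.03 (adjusted p = 0.0115), the transcription factor SMAD3 fell by 0.58 (adjusted p = 0.0488), and both called probe sets of PINK1, a mitochondrial kinase, fell by 0.78.

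A hypothesis was that one of the stable cell lines had gained or lost a chromosome segment, so that neighbouring genes changed together. Over 244 windows of 50 neighbouring bright genes in the gene order of GRCh38.p14, 4 windows lay beyond the limit of 0.19 from 1000 shuffled gene orders. Of these, 3 were higher, on chromosomes 6 and 7, and 1 was lower, on chromosome 11. Of the 35 splits of the arrays, 25 gave as many windows, up to 13, so windows of this kind are not particular to the real grouping. On chromosome X the consecutive windows from TIMP1 to TAFAZZIN were all lower (means -0.12 to -0.066 relative to all windows), none beyond the limit. That run was seen after the test and was not tested. The test cannot say whether a segment differs. Every other split mixes both groups, so a segment that differs between the lines would enter those splits in part. Neighbouring genes may also vary together between tumours of the same line, which was not tested.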
